A study of Gallus gallus with 3 samples.

How the data were processed

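Total RNA from jejunal mucosa was amplified, labelled with Cy3 or Cy5 and hybridised to 3 two-colour Agilent chicken arrays, all on 1 slide. By the labels, Cy5 carried normal-temperature RNA and Cy3 carried RNA of birds heated for 6 days on every array, with no dye swap, so a dye effect particular to a gene or probe stays in each ratio. Each array paired full sibs, and the 3 families shared a sire, per the labels. With a single slide there was no batch to test.

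Spots were quantified as intensity values by Agilent Feature Extraction 10.7.3.1, per the file headers, which deposited for each spot the mean signal and the median local background of both dyes, as well as processed signals that the scanner software had background-subtracted and dye-normalized with linear and lowess factors. The scanner software's ratio is a log10 of Cy5 over Cy3, per the file headers, and was set to 0 at 14.1%, 10.8% and 11.7% of spots on replicates 1, 2 and 3. The deposited series table holds log2 values with 43663 rows. Set against each array's scanner values over 43603 probes, every column had a slope of 1 and an intercept of 0 against the log2 of Cy3 over Cy5 processed signals, with medians of 0.0496, 0.0383 and 0.0544. The scale of the deposited table was thus settled from the data as Cy3 over Cy5 with no further centring; that this means heat over normal temperature rests on the labels alone. Further steps by the authors are not given in the sources used here. Probe positions are on galGal3, per the file headers, and are 1-based. No genome was used here, so exon or UTR annotation is not stated.

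From the mean signals and local backgrounds, intensities were corrected by normexp with an offset of 50 and normalized by loess within each array, with control spots at weight 0 (limma 3.58.1 in R 4.3.3). Spots flagged as outliers were removed, which were 7, 9 and 14 spots, and no spot was saturated. Spots of a probe were averaged. A probe was kept when well above background on all 3 arrays in at least 1 of the channels, which left 31984 of 43603 probes. The sign was turned so that a positive log2 ratio means a higher level in heat-stressed mucosa. Each probe's 3 ratios were fitted with an intercept by lmFit and eBayes, with a prior of 3.43 degrees of freedom, and adjusted by Benjamini-Hochberg over kept probes, with a threshold of 0.05. Errors given with gene values are the fit's moderated standard errors. The median standard error was 0.0804.

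Probe names came from RefSeq accessions through the GRCg7b gene table for 15152 probes, from a current symbol in the array files for 11012 and from a synonym of a single gene for 351, and 17088 kept the array's own name. In all, 27006 probes carried a gene name, and 10019 named genes had a kept probe. Each gene was represented by its brightest kept probe.

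In all, 33 gene lists were fixed before the data were examined. They were cytosolic chaperones and heat shock factors, mitochondrial chaperones and proteases, the endoplasmic reticulum unfolded protein response, antioxidant and redox genes, tight and adherens junctions, enterocyte transporters, brush border enzymes, lipid absorption, cholesterol synthesis, fatty acid oxidation, oxidative phosphorylation, ribosomal proteins, proteasome, cell cycle, inflammatory cytokines and defensins, interferon response, glucocorticoid-responsive genes, circadian clock, xenobiotic metabolism, and apoptosis and autophagy. Further lists held markers of crypt progenitors, goblet cells, enteroendocrine cells, T and natural killer cells, B and plasma cells, macrophages and granulocytes, smooth muscle, fibroblasts, endothelium, enteric neurons and glia, erythrocytes, exocrine pancreas and melanocytes. Camera tested each list with at least 5 measured genes at its preset correlation of 0.01, adjusted over lists. Camera with an estimated correlation and fry, which tests whether a list's genes move on balance 1 way without comparison to other genes, were run beside it. With 3 arrays the estimated correlation and its test rest on very few degrees of freedom, so that version could hardly call any list. A call lost there therefore says little about 1 list against another. Genes named in the text were to be the 10 highest and 10 lowest among those past the threshold with 1 sign on all 3 arrays and both channels well above background, filled up by smallest p where fewer passed. To these came up to 4 members of each list described, by smallest p, and 20 genes fixed in advance. Since no probe passed, no bounds for dim genes were called.

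Tests were tried on simulated data for this comparison: over 20 simulations of 31974 probes with independent noise drawn from the fitted prior, limma recovered 87.5% of 100 probes changed 2-fold and 98.8% of 100 changed 4-fold, with 11.2 false calls per simulation. Camera found a list shifted by 0.2 on the log2 scale in 20 of 20 simulations and called 0.05 of 33 unshifted lists on average. Real log ratios of genes on an array are correlated, which the simulation left out. It also changed 200 probes together and equally on all 3 arrays. Fewer changed probes face a stricter adjusted threshold, so the recovered shares do not show what the real comparison could miss. In the real data SLC26A3, 2.58-fold higher in heat, had a limma adjusted p = 0.620.

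The pairing was built into each ratio, as the labels give full sibs per array. After subtraction of the treatment means, the levels of both channels of an array correlated across probes at 0.905, 0.905 and 0.969. Both channels are read from the same spots, so these values cannot test the pairing of full sibs. Alternatives covered background correction, scanner-processed ratios, the deposited series table, median centring, quantile scaling of levels between arrays, filters on dim, flagged or saturated spots, the variance model, an unpaired fit, 1 value per gene, the set test and leaving out each array. Removal of a trend on the probes' base composition was added after seeing the data. For a list's percentile on a single array, 10000 random lists matched on level in 10 bins were drawn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.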

Results

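Gene expression was measured in the jejunal mucosa of female Xuefeng black-bone chickens, a Chinese breed with dark pigmented tissues, after 6 days of cyclic heat. Heat-stressed birds spent 8 h of each day at 37 ± 2 °C and the other 16 h at the normal temperature of 24 ± 2 °C, where control birds stayed throughout. Of 18 birds, 9 were in each treatment, and tissue was taken at 48 days of age. Each of 3 two-colour arrays set RNA of heat-stressed birds (Cy3) against RNA of their full sibs at normal temperature (Cy5), and the 3 families shared a sire. The labels do not say whether RNA of several birds was pooled on an array, so n = 3 counts arrays. The limma p-values rest on the spread between these 3 arrays combined with a prior taken from all kept probes. Camera p-values at the preset correlation compare a list's genes with other genes and do not measure the spread between arrays. Between 29335 and 31257 of 43603 probes were well above background in the heat channel and between 32770 and 33748 in the normal-temperature channel. The number of arrays limits the precision of every value.

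The comparison asks which transcripts of the jejunal mucosa differ between heat-stressed and normal-temperature birds. No single transcript passed the test. Camera called 11 of 33 gene lists, but with the sign of replicate 2 or of replicate 3 turned it called 14 and 17. The number of list calls therefore does not set the real comparison apart. Cytosolic chaperones were lower in heat-stressed mucosa, with a median log2 ratio of −0.21 over 39 genes and a median below 0 on each of the 3 arrays, a group call lost at adjusted p = 0.814 with an estimated correlation. Genes of the cell cycle (median −0.31, 62 genes), extracellular matrix (−0.24, 29 genes) and endothelium (−0.22, 15 genes) were lower over the 3 arrays. This shift came from replicates 1 and 2. On replicate 3 the lists ran the other way, with medians of 0.07, 0.09 and 0.03 and 7, 5 and 0 members below 0. There they lay at percentiles 100, 100 and 99.83 among random lists matched on level. T cell and natural killer cell genes (median 0.12, 26 genes) and brush border genes (0.12, 34 genes) were higher over the 3 arrays, but on replicate 3 they lay at 0.0056 and −0.12, and the brush border call ended without replicate 2. With median centring the medians were −0.18 and −0.46, where that of all kept probes was −0.20, and neither list was called. All kept probes are not the set camera compares, which is the brightest probe of each named gene. Against that set both lists still leaned higher. All of these group calls used a preset correlation between genes and were lost when that correlation was estimated from the 3 arrays. Camera in that form had little power with 3 arrays, with a smallest adjusted p of 0.814 over the 33 lists. The loss therefore does not weigh on 1 list more than another, and the calls rest on the preset correlation.

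**Figure D1:**
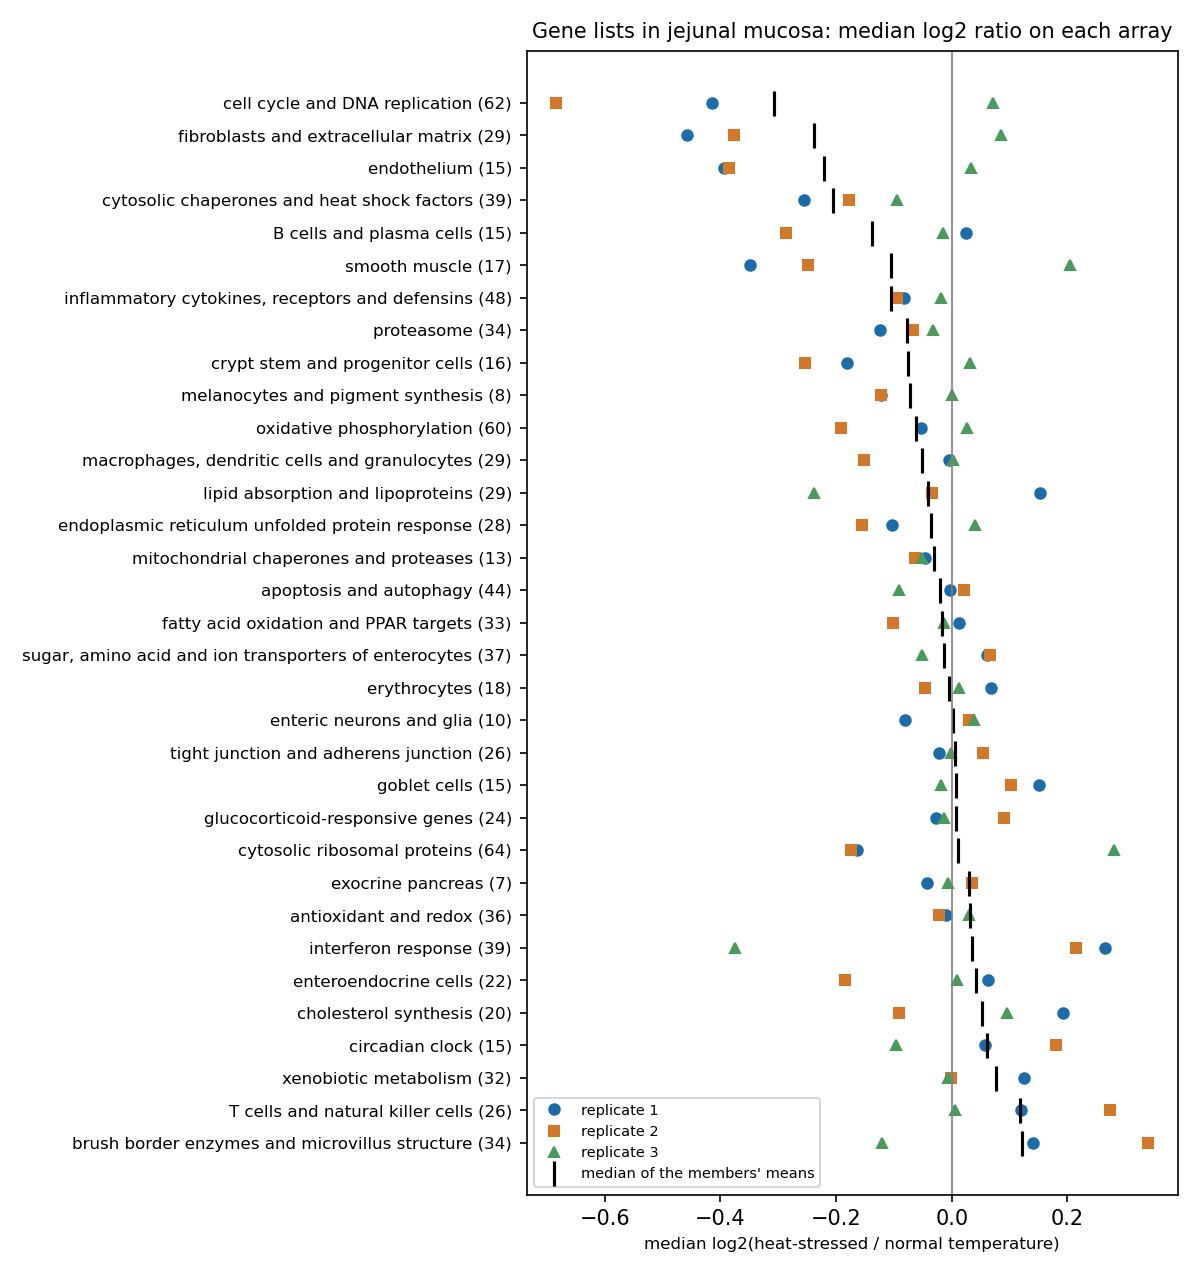
Median log2 ratio of heat-stressed over normal temperature (horizontal axis) for each of 33 gene lists (vertical axis, number of measured genes in brackets) on replicate 1 (circles), replicate 2 (squares) and replicate 3 (triangles), with the median of the members' 3-array means as a vertical bar. Cytosolic chaperones lay at −0.26, −0.18 and −0.09 on the 3 arrays, while the cell cycle list lay at −0.41 and −0.68 on replicates 1 and 2 and at 0.07 on replicate 3.

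Of 31984 probes tested, 0 were higher and 0 lower in heat-stressed mucosa at an adjusted p under 0.05 (limma with Benjamini-Hochberg adjustment). At an unadjusted p under 0.05 there were 1986, of which 591 were higher and 1395 lower, against 1599 that chance alone would give. That count hung on single arrays, with 823 without replicate 1, 738 without replicate 2 and 6321 without replicate 3. The limma fit with a trend and robust variances also called 0 probes, as did the unpaired fit of the 6 channels, with 2179 and 2162 at an unadjusted p under 0.05. The same sign on all 3 arrays was found for 10357 probes, or 32.4%, where chance gives 25%. That excess came from replicates 1 and 2, which shared a sign at 67.1% of probes. Replicate 3 shared its sign with replicate 1 at 47.5% and with replicate 2 at 50.2%. Normalization mattered more than the test: with median centring of each array in place of loess, 33 probes were higher and 10212 lower, and the median of all kept probes moved from −0.02 to −0.20.

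The 20 genes below had the smallest p in each direction among those with 1 sign on all 3 arrays, and none passed (limma adjusted p = 0.620 for each). SLC26A3, a chloride-bicarbonate exchanger of the apical membrane, had the highest log2 ratio among them, 1.37 ± 0.13 (SE, n = 3), a 2.58-fold higher level in heat. Its probe lies on galGal3 chromosome 1 from 15810430 to 15810489 and reads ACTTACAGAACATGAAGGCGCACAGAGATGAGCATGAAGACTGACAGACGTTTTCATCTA. The other kept probe of the gene gave 1.01. ENPEP, glutamyl aminopeptidase of the brush border, was at 0.60 ± 0.08 (SE, n = 3), and its 4 probes lay between 0.31 and 0.82. The bile acid receptor gene NR1H4 was at 0.57 ± 0.07, the sugar-phosphate exchanger gene SLC37A2 at 0.71 ± 0.09 and the monocarboxylate transporter family gene SLC16A5 at 0.57 ± 0.10. SLC25A39 (0.41), PIK3IP1 (0.38), PRRT1B (0.37), NPC2 (0.36) and MBNL1 (0.36) completed the higher genes, although 2 of 5 MBNL1 probes had the opposite sign.

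On the lower side, EXFABP, an extracellular fatty acid-binding lipocalin named P20K on the array, was at −1.25 ± 0.20 (SE, n = 3). CD72, a B cell surface receptor, was at −0.92 ± 0.17 (−1.52 without background subtraction and −1.81 with the scanner's ratios) and ATF4, a transcription factor of the integrated stress response, at −0.60 ± 0.08. Next came the proton channel gene HVCN1 at −0.55 ± 0.07 and the co-chaperone gene BAG3 at −0.53 ± 0.09. The MHC class II beta chain gene BLB2 was at −0.54 ± 0.09 at its brightest probe, but 4 of its 9 kept probes had the opposite sign, up to 1.13. MEMO1 (−0.50), CST3, which encodes cystatin C (−0.44), PDCD5 (−0.40) and HEXIM1 (−0.37) were the remaining genes. With median centring in place of loess, ENPEP (−0.16), PIK3IP1 (−0.24), SLC25A39 (−0.14), PRRT1B (−0.20), MBNL1 (−0.33) and NPC2 (−0.30) changed sign. SLC37A2 (0.15), SLC16A5 (0.080) and NR1H4 (0.067) came close to 0 there, SLC26A3 was at 0.94, and the 10 lower genes lay further down, from −0.91 for PDCD5 to −1.65 for EXFABP.

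**Figure D2:**
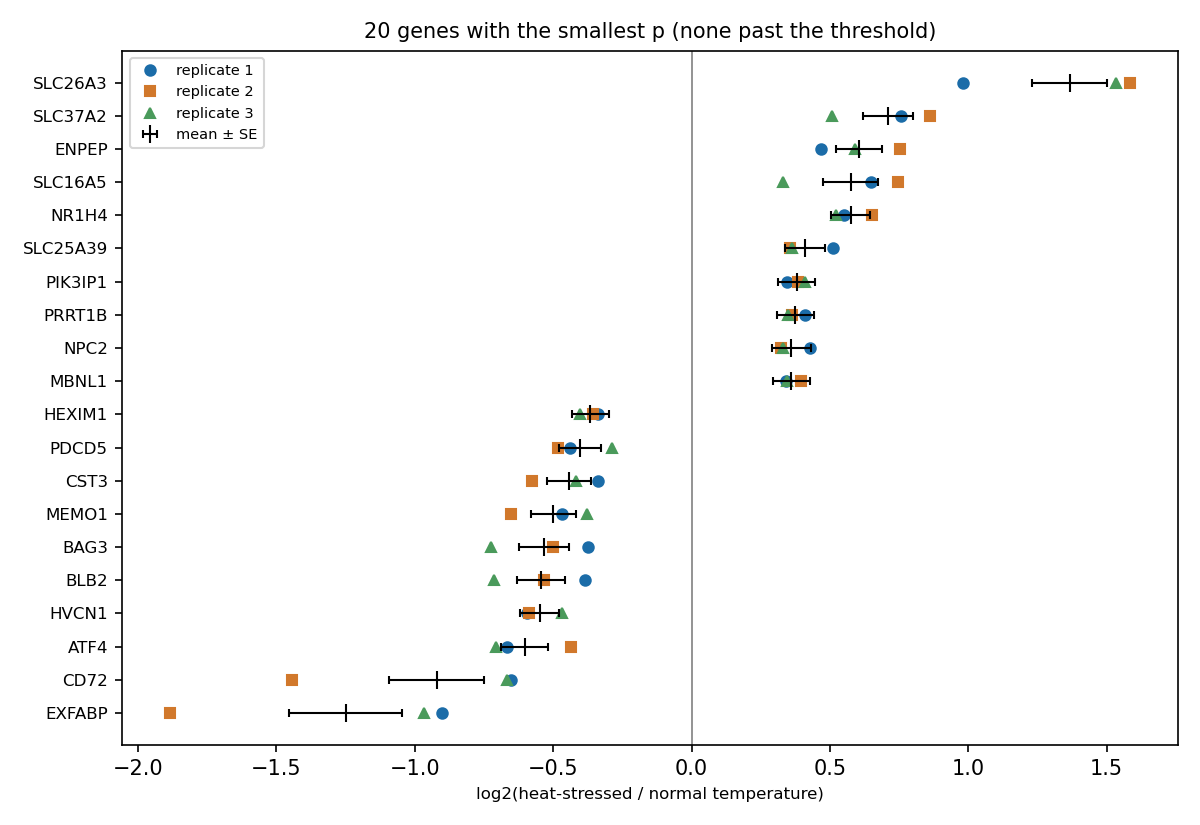
Log2 ratio of heat-stressed over normal temperature (horizontal axis) on replicates 1, 2 and 3 for the 20 genes (vertical axis) with the smallest p per direction, with the mean ± SE of 3 arrays in black. The values of SLC26A3 ran from 0.98 to 1.58 and those of EXFABP from −1.88 to −0.90, and no gene passed the adjusted threshold.

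Among cytosolic chaperones and heat shock factors, 34 of 39 measured genes had a mean ratio below 0. On all 3 arrays 16 were lower and 0 higher. HSPA8, the constitutive cytosolic HSP70 family member, was at −0.69 ± 0.16 (SE, n = 3), HSPA2, also of the HSP70 family, at −0.58 ± 0.12, and HSP90AA1, the stress-inducible cytosolic HSP90, at −0.52 ± 0.10. BAG3, which binds HSP70 proteins, was among the same 4 smallest p-values. After limma's test, 6 members passed when adjusted over the list alone (BAG3, HSP90AA1, HSPA2, HSPA8, TCP1 and DNAJA4, each at 0.0442), and 0 of the 13 with an unadjusted p under 0.05 passed over all probes. As a group the list was lower by camera (adjusted p = 5.2e-07). It was not called by camera with the correlation taken from the data (adjusted p = 0.814 with an estimated correlation), a form that could hardly call any list with 3 arrays. The HSPA8 probe lies on galGal3 chromosome 24 from 3116440 to 3116499, and all 4 kept HSPA8 probes were below 0, from −0.69 to −0.27. The list's median stayed below 0 without background subtraction (−0.18) and with the scanner's ratios (−0.17). With median centring it was −0.67, but there the median of all kept probes was −0.20 and 10212 probes were called lower against 33 higher. The kept sign under median centring is therefore no support for the shift.

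**Figure D3:**
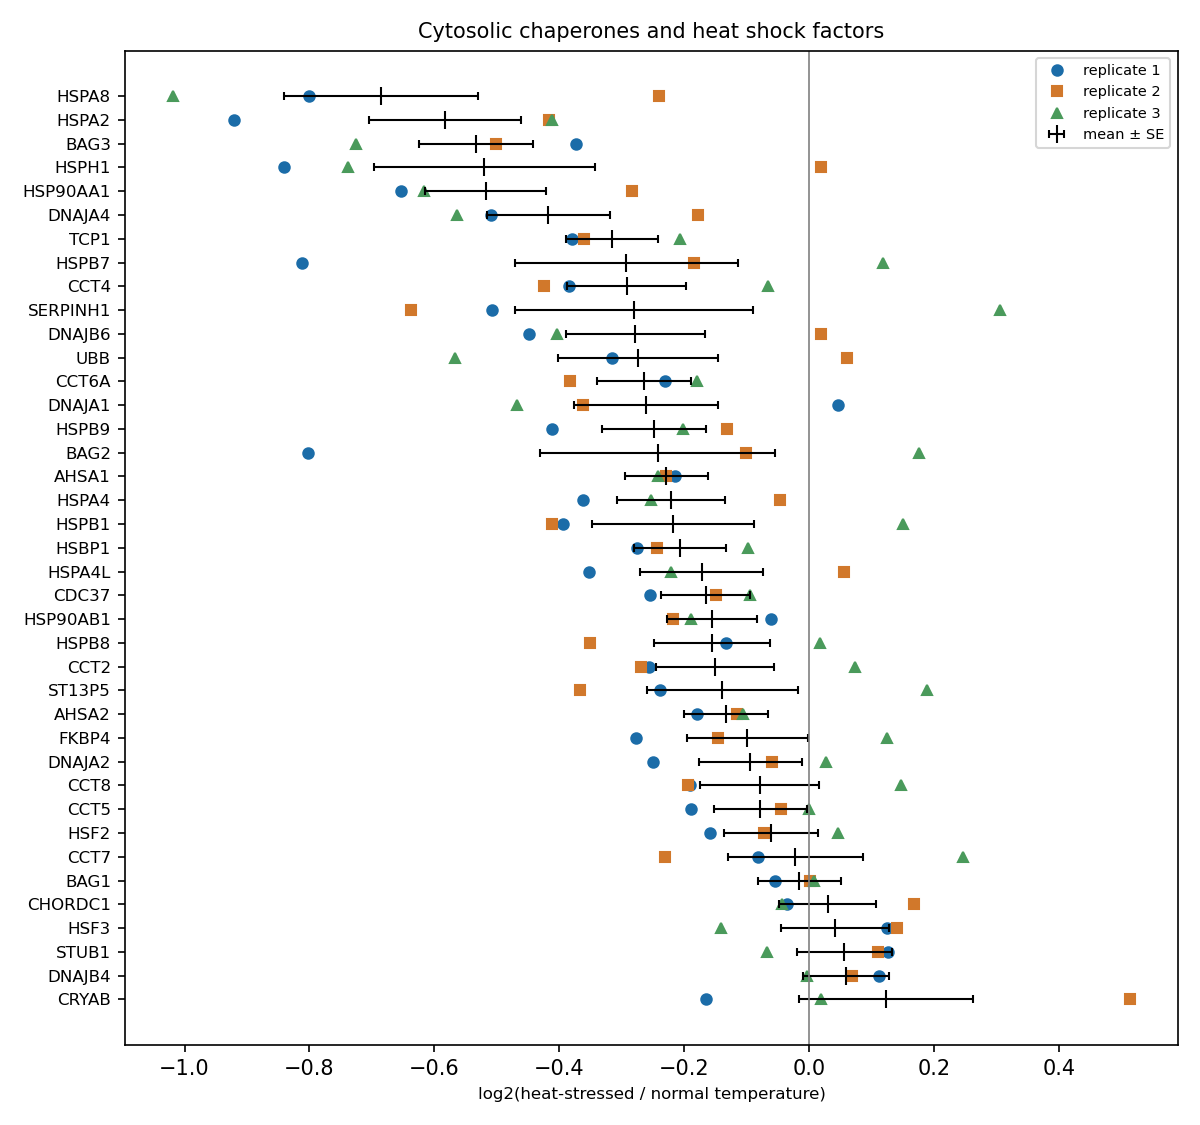
Log2 ratio of heat-stressed over normal temperature (horizontal axis) on replicates 1, 2 and 3 for 39 cytosolic chaperone and heat shock factor genes (vertical axis), with the mean ± SE of 3 arrays in black. Means ran from −0.69 for HSPA8 to 0.12 for CRYAB, and 34 of 39 were below 0.

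Genes of the cell cycle and DNA replication were mostly lower, with 60 of 62 means below 0, but only 6 genes were lower on all 3 arrays. The list's median was −0.41 on replicate 1, −0.68 on replicate 2 and 0.07 on replicate 3. RRM1, a subunit of ribonucleotide reductase, was at −0.47 ± 0.13 (SE, n = 3) with 1 of its 4 probes above 0, CDC45, a replication fork helicase component, at −0.52 ± 0.19 and CCND1, cyclin D1, at −0.31 ± 0.11. None of the 62 passed adjusted over the list alone (8 at an unadjusted p under 0.05 by limma) and 0 passed over all probes. The group was lower by camera (adjusted p = 3.43e-11; adjusted p = 0.814 with an estimated correlation).

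Markers of fibroblasts and extracellular matrix, endothelium and smooth muscle moved with the cell cycle list on each array. Matrix genes had medians of −0.46, −0.38 and 0.09 on replicates 1, 2 and 3, endothelial genes −0.39, −0.38 and 0.03, and smooth muscle genes −0.35, −0.25 and 0.20. FBLN1, which encodes the matrix protein fibulin, was at −0.38 ± 0.07 (SE, n = 3) and COL6A1, a type VI collagen chain, at −0.41 ± 0.15. The endothelial genes EGFL7 and KDR, the latter a VEGF receptor, were at −0.39 ± 0.14 and −0.36 ± 0.15, and CALD1, caldesmon of smooth muscle, at −0.43 ± 0.12. By camera, the matrix list (adjusted p = 0.00256) and the endothelial list (adjusted p = 8.65e-05) were lower and the smooth muscle list did not pass (adjusted p = 0.125). The called pair gave an adjusted p = 0.814 with an estimated correlation each, and 0 members of the 3 lists passed adjusted over the list alone or over all probes by limma, with 5, 2 and 2 at an unadjusted p under 0.05. Without replicate 1 the matrix list lost its call (median −0.07, adjusted p = 0.583), and without replicate 2 too (−0.14, adjusted p = 0.0548). With median centring neither the matrix (adjusted p = 0.232) nor the endothelial list (0.835) was called. The smooth muscle list was called lower without replicate 3 (median −0.27, adjusted p = 2.29e-05; adjusted p = 0.726 with an estimated correlation) and with the mean of each gene's probes (−0.16, 0.0344; adjusted p = 0.739 with an estimated correlation).

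Brush border enzymes and microvillus genes were higher as a group, with 9 of 34 means below 0, and again the arrays differed, at 0.14, 0.34 and −0.12. ACE, a brush border peptidase, was at 0.77 ± 0.21 (SE, n = 3) and ENPEP passed limma's test adjusted over the list alone (0.0182), the only one of 4 with an unadjusted p under 0.05, while 0 passed over all probes. ANPEP, aminopeptidase N, was at −0.40 ± 0.15 at its brightest probe, but 5 of its 6 probes were of the other sign. The camera call for the list (adjusted p = 0.00166; adjusted p = 0.814 with an estimated correlation) ended without replicate 2 (median −0.023, adjusted p = 0.937), with median centring (−0.46, 0.794) and narrowly with the scanner's own ratios (0.13, 0.0537). Enterocyte transporters went both ways and did not pass as a list (adjusted p = 0.488), with a median of −0.014, a mean of 0.06 and a test leaning higher. SLC26A3 passed adjusted over the list alone (0.0036), 1 of 8 at an unadjusted p under 0.05 by limma, and 0 passed over all probes. In the same list the dicarboxylate transporter gene SLC13A2 was at 1.35 ± 0.27 and the water channel gene AQP1 at −0.62 ± 0.14.

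Genes of T cells and natural killer cells were higher as a group, with 22 of 26 means above 0 and 11 higher on all 3 arrays. CD3E, a T cell receptor complex chain, was at 0.46 ± 0.09 (SE, n = 3), GZMA, granzyme A, at 0.53 ± 0.12 and CD8BP, a CD8 beta chain, at 0.49 ± 0.12. The list's medians were 0.12, 0.27 and 0.01 on the 3 arrays, and camera called it (adjusted p = 9.45e-06; adjusted p = 0.814 with an estimated correlation). By limma, 0 of the 4 members with an unadjusted p under 0.05 passed adjusted over the list alone or over all probes. With median centring the list's median was −0.18, against −0.20 for all probes, and camera did not call it (adjusted p = 0.172). Camera compares the brightest probe of each named gene, not all probes, and there the list still leaned higher. B cell and plasma cell genes did not pass (adjusted p = 0.358), with CD79B, a B cell receptor chain, at −0.37 ± 0.09 and the B cell survival factor gene TNFSF13B at −0.35 ± 0.09; by limma 0 of its 4 members with an unadjusted p under 0.05 passed adjusted over the list alone or over all probes.

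Cholesterol synthesis genes were higher by camera (adjusted p = 0.0143), as were xenobiotic metabolism genes (0.0336) and circadian clock genes (0.0438), with medians of 0.05, 0.08 and 0.06. All 3 calls were lost with the correlation taken from the data (adjusted p = 0.814 with an estimated correlation). For cholesterol synthesis and xenobiotic metabolism the direction of the test turned with median centring (medians −0.42 and −0.43), and the clock list's median also fell below 0 there (−0.24). INSIG1, a sterol-sensing regulator, was at 0.40 ± 0.08 (SE, n = 3), CYP3A5, a cytochrome P450 named CYP3A7 on the array, at 0.41 ± 0.09 and NR1D2, a clock repressor, at 0.40 ± 0.11. Some members ran against their list: the clock kinase gene CSNK1D, with the smallest p there, was at −0.35 ± 0.08 with 2 of its 4 probes above 0, and the acetyltransferase gene NAT was at −0.22 ± 0.07. CYP24A1, lower at an unadjusted p under 0.05, was well above background in the heat channel on 0 of 3 arrays and is given no ratio. Oxidative phosphorylation and proteasome genes were slightly lower (camera adjusted p = 0.0438 each), with medians of −0.06 over 60 genes and −0.08 over 34. Their adjusted p = 0.854 and 0.814 with an estimated correlation. NDUFS4, a complex I subunit, was at −0.37 ± 0.07 with 1 of its 2 probes at 0.13, and PSMD6 of the proteasome at −0.21 ± 0.07. By limma, 0 members of these 5 lists passed adjusted over the list alone or over all probes, with 4 at an unadjusted p under 0.05 in each of cholesterol synthesis, xenobiotic metabolism, clock and proteasome and 6 in oxidative phosphorylation.
Each of these 5 lists lost its call without 1 array or another. The cholesterol median was −0.0059 without replicate 1 (adjusted p = 0.441) and 0.06 without replicate 3 (0.135). Xenobiotic metabolism was at 0.024 (0.441) and 0.12 (0.085) without the same arrays, and the proteasome at −0.04 (0.597) and −0.08 (0.056). Oxidative phosphorylation was at −0.08 without replicate 1 (adjusted p = 0.0929) and 0.0015 without replicate 2 (0.992), and the clock at −0.025 without replicate 2 (0.804).

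The unfolded protein response list of the endoplasmic reticulum did not pass (adjusted p = 0.307). ATF4 passed limma's test adjusted over the list alone (0.0157), 1 of 4 at an unadjusted p under 0.05, and 0 passed over all probes; ASNS, asparagine synthetase and a target of ATF4, was at −0.29 ± 0.08 (SE, n = 3) and CHAC1, another, at −0.24 ± 0.07 (−0.38 without background subtraction). In the interferon response list (adjusted p = 0.21) BLB2 passed limma's test adjusted over the list alone (0.0461), 1 of 5 at an unadjusted p under 0.05, and 0 passed over all probes. BLB2 was lower at its brightest probe, while others of its kept probes had the opposite sign. In the list of macrophages, dendritic cells and granulocytes (adjusted p = 0.572) EXFABP passed adjusted over the list alone (0.0357), 1 of 7, and 0 passed over all probes. Other lists with 0 members passing adjusted over the list alone or over all probes by limma, and with no camera call, were inflammatory cytokines, receptors and defensins (adjusted p = 0.204), antioxidant and redox (0.234), glucocorticoid-responsive genes (0.311), goblet cells (0.311), melanocytes and pigment synthesis (0.488), crypt stem and progenitor cells (0.525) and exocrine pancreas (0.569). The same held for mitochondrial chaperones and proteases (0.572), tight and adherens junctions (0.572), erythrocytes (0.575), apoptosis and autophagy (0.586) and enteroendocrine cells (0.713). Lipid absorption and lipoproteins, fatty acid oxidation and PPAR targets, cytosolic ribosomal proteins and enteric neurons and glia each had an adjusted p = 0.963. Members with an unadjusted p under 0.05 in these 16 lists numbered between 0 and 5 per list. Median and mean had opposite signs, with the test leaning higher, for tight junctions (0.0061 and −0.029), ribosomal proteins (0.011 and −0.027), enteroendocrine cells (0.043 and −0.024), neurons and glia (0.0027 and −0.019) and erythrocytes (−0.0044 and 0.0064). For lipid absorption both lay below 0 (−0.041 and −0.034) while the test leaned higher.
Several of these lists were called under another setting. With median centring the unfolded protein response (median −0.53, adjusted p = 0.000691), mitochondrial chaperones (−0.57, 0.0338) and ribosomal proteins (−0.81, 4.71e-14) were lower and exocrine pancreas (0.075, 0.0146) higher, each with an adjusted p = 0.925 with an estimated correlation. Ribosomal proteins were higher without replicate 1 (0.064, 0.0149) or 2 (0.077, 0.0189) and lower without replicate 3 (−0.15, 8e-06), with adjusted p = 0.915, 0.988 and 0.726 with an estimated correlation. Lipid absorption was lower without replicate 1 (−0.075, 0.0116) and erythrocyte genes higher without replicate 2 (0.070, 0.0472), with adjusted p = 0.915 and 0.988 with an estimated correlation. Interferon response genes were higher without replicate 3 (0.22, 1.82e-09) and with the mean of each gene's probes (0.062, 0.0105), with adjusted p = 0.726 and 0.739 with an estimated correlation.

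Genes fixed for heat stress and gut function, whatever their values, had mean ratios that did not pass limma's test. Besides those above, HSPH1 was at −0.52 ± 0.18 (SE, n = 3), the small heat shock protein gene HSPB1 at −0.22 ± 0.13, the mitochondrial chaperonin gene HSPD1 at −0.30 ± 0.26 and the endoplasmic reticulum chaperone gene HSPA5 at −0.31 ± 0.14. None of these was below 0 on every array. HSPH1 was at 0.02 on replicate 2, and HSPB1, HSPD1 and HSPA5 were at 0.15, 0.50 and 0.09 on replicate 3. HSF1 had no kept probe under that name. The peptide transporter gene SLC15A1 was at 1.05 ± 0.35, from 1.44 and 1.76 on replicates 1 and 2 and −0.05 on replicate 3. Glucose transporter genes had small means, SLC5A1 at −0.08 ± 0.23 and SLC2A2 at 0.20 ± 0.20, but their arrays differed. SLC5A1 went from 0.46 on replicate 1 to −0.75 on replicate 3, and SLC2A2 from 0.83 on replicate 1 to −0.16 on replicate 2. Sucrase-isomaltase (SI) was near 0 at 0.12 ± 0.08, with 1 of its 2 probes below 0. FABP2, the intestinal fatty acid-binding protein gene, was lower on all 3 arrays at −0.37 ± 0.09, whereas the apolipoprotein gene APOA4 was at −0.55 ± 0.87, from 2.19 on replicate 1 to −2.64 on replicate 3. The junction genes OCLN (0.10 ± 0.11), TJP1 (0.07 ± 0.07, 2 of 4 probes below 0) and CLDN1 (−0.07 ± 0.12), the mucin gene MUC2 (0.04 ± 0.18) and SOD1 (−0.13 ± 0.10) all had means near 0. Of these, MUC2 ran from 0.38 on replicate 2 to −0.51 on replicate 3, and OCLN and CLDN1 also differed in sign between arrays. Without background subtraction TJP1 was at 0.14, CLDN1 at −0.19, MUC2 at 0.011 and SLC2A2 at 0.10, and with the scanner's ratios OCLN was at 0.16, TJP1 at 0.18, CLDN1 at −0.20, MUC2 at 0.017 and SOD1 at −0.069. IL1B was at −0.12 ± 0.07 and was well above background in the heat channel on 2 of 3 arrays, and it was at −0.24 without background subtraction and −0.62 with the scanner's ratios. Among these genes, SI, OCLN, TJP1, MUC2 and IL1B changed sign with median centring, and SLC5A1, SLC2A2, APOA4, CLDN1 and MUC2 changed sign when a single array was left out.

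The arrays, on each of which family, tissue sample and labelling coincide, differed in how their log ratios ran. Across kept probes, which are not independent replicates, Pearson's r was 0.375 between replicates 1 and 2, −0.110 between 1 and 3 and −0.0659 between 2 and 3. The SD of log ratios was 0.245, 0.274 and 0.165 on the 3 arrays.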

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

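The probe base composition setting was chosen after seeing the data. By limma, 0 probes were called on either side without background subtraction, with the other filters, the trend and robust fit, 1 value per gene, base composition removed, no replicate block and each left-out array, with between 738 (without replicate 2) and 6321 (without replicate 3) at an unadjusted p under 0.05. The scanner software's ratios and the deposited series values called 5 higher and 0 lower each. For the scanner ratios these were PCDH10, named after its values were seen, and 4 probes without a gene symbol, all well above background in heat and on 0 arrays at normal temperature. Their scanner log2 ratios of 3.01 to 3.73 thus rest on a normal-temperature signal not well above background. In the main fit the same probes were at 0.26 to 0.44 (limma adjusted p = 0.62 for each). Median centring called 33 higher and 10212 lower, so higher calls were 0.322% of the total. A threshold of an unadjusted p under 0.05 and 2-fold gave 11 higher and 8 lower. The 11 list calls became 6 with the scanner ratios, 6 with the deposited values, 0 with an estimated correlation and 0 with fry (chaperones alone at an unadjusted p under 0.05). Without replicates 1, 2 and 3 in turn, 8, 9 and 11 lists were called, of which 6, 7 and 8 were among the 11, and median centring called 8, of which 4 were. Both scanner-based sets ended the calls of brush border, oxidative phosphorylation, proteasome, clock and xenobiotic metabolism. Clock and xenobiotic metabolism also lost theirs without background subtraction (adjusted p = 0.224 and 0.105) and with no filter on dim probes (0.0891 each), and the clock with the stricter filter (0.0528). The trend and robust fit ended oxidative phosphorylation (0.127), proteasome (0.114) and clock (0.0544), and the mean of a gene's probes ended oxidative phosphorylation (0.0649). Chaperones, cell cycle, endothelium and T cells kept theirs without each array. The cause of these differences was not tested.
The fit without the pairing, that is with no replicate block, called 0 probes higher and 0 lower and 10 lists, and of the 11 list calls it ended that of oxidative phosphorylation (adjusted p = 0.056).
With median centring, signs turned for ENPEP (−0.16), PIK3IP1 (−0.24), SLC25A39 (−0.14), PRRT1B (−0.20), MBNL1 (−0.33), NPC2 (−0.30), SI (−0.69), OCLN (−0.38), TJP1 (−0.28), MUC2 (−0.41), IL1B (0.13), USH1C (−0.31), INSIG1 (−0.20), MSMO1 (−0.37), SREBF2 (−0.53), LSS (−0.46), HLF (−0.018), CRY2 (−0.43), CYP3A5 (−0.14), ABCG2 (−0.056), CD3E (−0.25), GZMA (−0.24), CD8BP (−0.010), CD247 (−0.32), TAP1 (−0.28), BF2 (−0.26), PGM5 (−0.11) and HOPX (−0.14), and for the lists of cholesterol synthesis (−0.42) and xenobiotic metabolism (−0.43). Without 1 array, SLC2A2 ranged from −0.11 to 0.39, CLDN1 from −0.23 to 0.026, MUC2 from −0.12 to 0.32, SLC5A1 from −0.34 to 0.26 and APOA4 from −1.92 to 0.49. The rest of the 106 genes recomputed kept their sign in every setting run; TCP1, DNAJA4 and CRYAB were not recomputed, and PCDH10 was with the scanner ratios alone. Quantile scaling between arrays and removal of saturated spots moved no ratio, so they test nothing here.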

Other observations

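The tests of dyes reversed on all arrays and of a share of deeper tissue, and the removal of base composition, were chosen after the result was seen. Interferon response genes, which mark antiviral and antigen presentation programmes, had medians of 0.27 and 0.22 on replicates 1 and 2 and −0.38 on replicate 3, with 35 of 39 members below 0 there. Cytosolic ribosomal protein genes ran the other way, at −0.16 and −0.18 against 0.28. Neither list passed over the 3 arrays by camera (adjusted p = 0.21 and 0.963; adjusted p = 0.879 and 0.994 with an estimated correlation). Without replicate 3 interferon genes were called higher and ribosomal genes lower (1.82e-09 and 8e-06; adjusted p = 0.726 with an estimated correlation for both), and ribosomal genes were called higher without replicate 1 or 2 (0.0149 and 0.0189; adjusted p = 0.915 and 0.988 with an estimated correlation).

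Some genes of other groups had 1 sign on each array without passing limma's test. SLC10A2, the ileal bile acid transporter gene, was at 1.06 ± 0.22 (SE, n = 3), alongside the bile acid receptor gene NR1H4 at 0.57 ± 0.07. OLFM4, a marker of crypt stem cells in mammals, was at −0.67 ± 0.19, from −0.26 on replicate 3 to −1.25 on replicate 2. HOPX of the same uncalled list went the other way, at 0.33 ± 0.13. CD74, the MHC class II invariant chain gene, was at −0.78 ± 0.26, although 1 of its 2 probes was at 0.32. B cell genes CR2, a complement receptor, and POU2AF1, a transcriptional coactivator, were at −0.36 ± 0.12 and −0.51 ± 0.19. The POU2AF1 mean leaned on replicate 2, at −1.09 there against −0.25 and −0.20 on replicates 1 and 3.

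The median of the chaperone list was below 0 on each array, with 35, 29 and 25 of 39 members below 0, and its call was lost at adjusted p = 0.814 with an estimated correlation. A linear trend on probe base counts accounted for little of the shift, since the list's median was −0.17 once it was removed. That trend was small on every array, with R squared of 0.024, 0.020 and 0.0031, so its removal could move little. Other effects of base composition were not tested. Dye effects of single probes are argued against by 64 other probes of 31 of these genes, with a median of −0.17 (SD 0.158) and 55 below 0. A dye effect shared by a whole transcript, or dyes reversed on all 3 arrays, cannot be told apart from an effect of heat, because 0 arrays carried the dyes the other way. The hour of sampling relative to the daily heat, which bears on chaperone transcripts, is not given.

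Replicate 3 departed from replicates 1 and 2. Of the 200 genes with the largest shared ratio on replicates 1 and 2, 57 (28.5%) had the same sign on replicate 3, between the bounds of 25% and 50% set for reversed and unreversed dyes. Over the same genes, r between replicate 3 and the mean of replicates 1 and 2 was 0.0423, where reversed dyes would give a negative r, so dyes reversed on that array alone are not settled by these values. Another share of deeper tissue layers may also account for it, with 11 of 12 medians of fibroblast, endothelium, smooth muscle and neuron lists on the predicted side, but it was framed on these values and stays open. A difference between families, which the design names, was not tested.

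With 3 arrays there are 4 ways of turning their signs, too few for a share under 0.05: 0 probes were called in the real arrangement and at most 0 in the others, 4 of 4 as many, and 1986 and 3343 at an unadjusted p under 0.05 by limma. For lists the real value was 11 and the highest other 17, with replicate 3 turned, and 3 of 4 arrangements gave as many. The number of list calls thus does not set the real arrangement apart from the others. The 10 splits of the 6 channels are also too few, with 0 probes in the real split and 5 in the highest other, and 10 of 10 as many.

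Spike-in transcripts, 10 in 320 spots per array, had median log2 ratios of Cy3 over Cy5 processed signals of 0.35, 0.36 and −0.21 on replicates 1, 2 and 3. The scanner software had dye-normalized these signals, so the ratios also carry each array's normalization. Per transcript, replicate 3 differed from replicate 1 by −0.51 in the median, from −0.60 to −0.41, and replicate 2 by −0.04.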
